A study of Homo sapiens with 18 samples.

How the data were processed

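RNA of MCF-7/c-Jun cells was hybridised, per the labels' protocols, after conversion to sense-strand cDNA with the Ambion WT Expression kit and labelling with biotin. The authors deposited 1 value per array and row of the array, on a log2 scale with 2 decimals. Per the submitters' processing notes, Transcriptome Analysis Console and PLIER were used, with no versions and no roles stated. Background correction, normalization, summary of probes and genome build are not given in the sources used here. The log2 values were used as deposited, without another normalization, and ran from 1.5 to 19.93. Any scaling the authors applied across arrays would remove a change shared by most genes, so that a change is relative to the other genes of the array.

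The table held 138745 rows for 18 arrays, of which 2995 were control rows. Names came from the platform annotation kept by GEO, which can be old, and symbols were checked against NCBI RefSeq genes through their gene identifiers, where 25516 rows matched. In total 36176 rows carried 1 gene symbol, 1119 carried several and were not named, and 98455 are unnamed here. Where a gene had several rows (1576 genes), the row with the highest mean over all arrays was used, which gave 33616 genes, 17381 of them protein coding. No filter on dim rows was applied. For a called difference of a named gene whose dimmer group mean lay at or below the 95th percentile of the negative control rows, a lower bound was computed as the brighter mean minus the dimmer group's mean of, per array, the higher of its signal and that percentile, and no difference is given where both means lay at or below it, apart from that of THAP11. The 612 negative control rows give the background of the arrays. Coordinates are not printed, since the build of the rows is not given in the sources used here.

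Groups came from the sample titles, which give the treatment, the tetracycline state and a replicate number. limma (version 3.58.1, R 4.3.3) was fitted to all 18 arrays with a mean for each of the 6 groups, lmFit, and eBayes with an intensity trend, with 12 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within each of 11 contrasts: -Tet minus +Tet in each of 3 treatments, E2 minus vehicle and tamoxifen minus vehicle in each state, tamoxifen minus E2 in each state, and the difference between the states in the response to E2 and to tamoxifen. The labels call the arrays biological replicates but do not say how the cultures were kept apart, so p-values measure the spread between these arrays.

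The 21 gene lists, the rule for named genes and the tests were fixed before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over the 21 lists within a contrast, and with fry. The rule named JUN, ESR1, TFF1, PGR, GREB1, CCND1 and MYC, the 6 called genes with the largest rise and the 6 with the largest fall in each of 7 main comparisons, and 3 members of each list with at least 3 calls or a camera adjusted p under 0.05, up to 30 genes. In the other comparisons it named JUN and the 3 largest rises and falls. Members of lists that lay only on rows with several symbols were not measured, such as HMGCR and LDLR of the sterol list and KRT17 of the basal list.

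The scripts were tested on simulated data for the same 33616 genes, with 50 genes changed by each of 4 sizes. For -Tet against +Tet in vehicle, changes of 0.5 on the log2 scale were recovered in 10% of genes, of 1 in 54% and of 2 in 100%. For E2 in +Tet the shares were 8%, 64% and 100%, and for tamoxifen in +Tet 12%, 78% and 98%. The adjusted threshold loosens as more genes pass. The simulations called 142 genes in vehicle, where the data gave 321, and 144 with E2, where the data gave 3521. Shares for the data, above all with E2, can thus be understated. The correlation expected from shared vehicle arrays came from 50 simulations of unchanged groups.

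Alternatives tried were quantile normalization, centring of each array on its median, the mean of all rows of a gene, genes with a mean above the median gene, a prior variance without trend, array weights, a fold minimum of 1.5, only the arrays compared in the fit, the replicate number as a block, and each array left out in turn. Others were added after the data were seen: leaving out the pair of arrays of lowest weight, and testing only genes above the 95th percentile of the negative control rows. A fit without 1 array has fewer arrays in that group, so that a lower count or a lost call can come from the smaller group alone. A pseudocount for linear values was not applied, because the values were already log2. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.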

Results

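Gene expression was measured on 18 whole-transcript arrays of MCF-7/c-Jun cells, a derivative of the estrogen receptor-positive breast cancer line MCF-7 kept with tetracycline (+Tet, 2 ug/ml) or without it (-Tet). By the name of the line and the title of the study, withdrawal of tetracycline is taken to switch on c-Jun, a subunit of the AP-1 transcription factor. Cells of both states were held in steroid-depleted medium for 72 h and then given ethanol vehicle, 10 nM estradiol (E2) or 1 uM tamoxifen, a ligand of the estrogen receptor used against breast cancer, for 24 h. Each of the 6 groups held 3 arrays, which the labels call biological replicates. Array medians lay between 3.49 and 3.54 on the log2 scale. The negative control rows had a median of 3.975 and a 95th percentile of 6.12, and the mean of 10475 of the 33616 genes tested lay above that percentile. Where the dimmer group of a called difference lay at or below it, the difference is a lower bound, written as at least the distance from that percentile. The number of arrays limits the precision of every value below. Changes are log2 differences ± standard error from 1 limma fit of all 18 arrays, and levels are means ± SD of 3 arrays.

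The first question was whether JUN itself differed between the states. Its signal was 10.87 ± 0.48 (SD, n = 3) in vehicle +Tet and 10.51 ± 0.28 (SD, n = 3) in vehicle -Tet. The difference, -Tet minus +Tet, was -0.36 ± 0.30 in vehicle (adjusted p = 0.884), -0.85 ± 0.30 in E2 (adjusted p = 0.238) and -0.47 ± 0.30 in tamoxifen (adjusted p = 0.642). JUN was thus not higher on the arrays labelled -Tet, against the direction the labels imply, and the arrays are called by their labels throughout. The table holds 1 JUN row, and whether it reads the part of the transcript carried by the vector is not given in the sources used here. Presence of tetracycline and the intended c-Jun state coincide in all arrays, so that no comparison separates them.

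**Figure D1:**
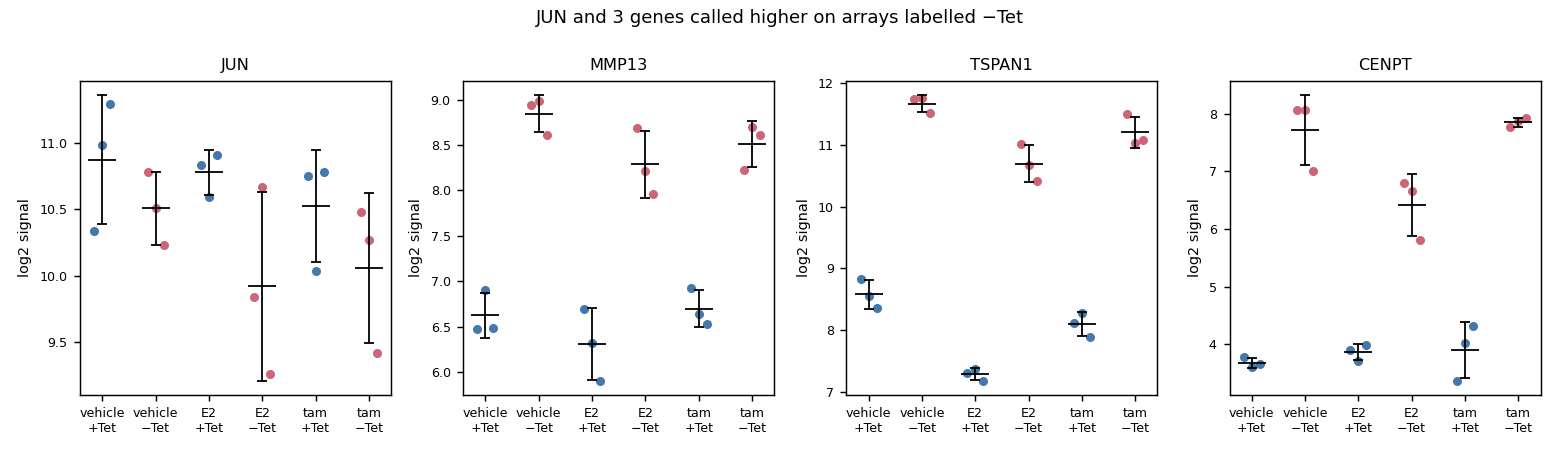
Log2 signal (y axis) of JUN, MMP13, TSPAN1 and CENPT on each array of the 6 groups (x axis), with points for single arrays, blue for +Tet and red for -Tet, and bars for the mean and SD of 3 arrays. JUN overlaps between the states in vehicle, at 10.87 and 10.51 on average, while TSPAN1 averages 8.58 in vehicle +Tet and 11.67 in vehicle -Tet.

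Among the genes with large rises on arrays labelled -Tet in vehicle, CENPT, which encodes a kinetochore protein, reached 7.71 ± 0.61 (SD, n = 3) from a signal not above the negative controls, a rise of at least 1.59 (adjusted p = 1.02e-09). TSPAN1, a tetraspanin, rose by 3.10 ± 0.19 (adjusted p = 1.62e-10) and TGFBI, a matrix protein, by 3.04 ± 0.21 (adjusted p = 1.05e-09). SNAI2, a repressor linked to epithelial-mesenchymal transition, rose by 2.92 ± 0.23, the adhesion gene CEACAM5 by 2.55 ± 0.17 and ENTPD3 by 2.51 ± 0.25. In the list of AP-1 target genes 3 of 26 measured members were higher and none was lower (camera adjusted p = 7.91e-07, and 0.0337 with an estimated correlation). Adjusted over the list alone, 8 were higher. The list is dim, with a median level of 4.70, and these 8 include TGFA and SPRR1B, which lay above the negative controls in no group. The 3 members called over all genes were the collagenase gene MMP13, up by 2.22 ± 0.23, the cytokine gene IL6, up by at least 0.67, and the integrin gene ITGA2, up by 0.69 ± 0.16. The ITGA2 call was lost in 5 of the 6 fits that left out 1 array, with an adjusted p of up to 0.177 without vehicle +Tet replicate 2.

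Genes of cell division were lower on the same arrays. In the list of mitosis and G2/M genes 22 of 28 members fell and none rose, with a median change of -0.898 (camera adjusted p = 5.57e-05 with an estimated correlation), and 28 were lower when adjusted over the list alone. CDC20, an activator of the anaphase-promoting complex, changed by -1.49 ± 0.16, TOP2A by -1.0 ± 0.13 and DLGAP5 by -1.21 ± 0.16. Of 31 DNA replication and S phase genes 9 fell and none rose, with a median of -0.677 (camera adjusted p = 0.00178 with an estimated correlation), and 23 were lower when adjusted over the list alone. TK1 changed by -1.18 ± 0.17 and RRM2 by -1.08 ± 0.18, both enzymes of nucleotide supply. In the sterol and lipid synthesis list 3 of 26 members fell, with a median of -0.307 (camera adjusted p = 1.01e-08, but adjusted p = 0.054 with an estimated correlation), and 6 were lower and 1 higher when adjusted over the list alone. FADS2 was lower by -0.79 ± 0.15, EBP by -0.69 and TM7SF2 by -0.61. Of the 6 fits that left out 1 array, the TM7SF2 call was lost in 5, with an adjusted p of up to 0.252 without vehicle -Tet replicate 3, the EBP call in 2, up to 0.0999 without vehicle -Tet replicate 2, and the FADS2 call in 2, up to 0.0543 without vehicle +Tet replicate 3. Single genes with large falls included UPK1A, at -1.48 ± 0.24, the trefoil factor TFF3, at -1.46 ± 0.18, the immediate early gene EGR1, at -1.46 ± 0.22, and the centromere gene HJURP, at -1.42 ± 0.17.

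ESR1, the estrogen receptor gene, did not pass the test between the states in vehicle, at -0.54 ± 0.33 (adjusted p = 0.788). Neither did TFF1, at -0.23 ± 0.12, GREB1, at -0.72 ± 0.20 (adjusted p = 0.11), CCND1, at -0.28 ± 0.12, or MYC, at 0.22 ± 0.23. PGR was not above the negative controls in either state. In all, 321 of 33616 genes differed between the states in vehicle, 133 higher and 188 lower in -Tet. After quantile normalization the split was 202 higher and 167 lower. The count fell to between 190 and 224 when 1 of the 6 arrays was left out, and for 4 of those arrays it moved by over 1.5 times. It was 190 and 201 without vehicle +Tet replicates 2 and 3, and 206 and 197 without vehicle -Tet replicates 2 and 3. The count fell in each of these 6 fits, and a smaller group lowers it by itself, so these arrays are not singled out.

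The same contrast in E2 gave 266 genes, 143 higher and 123 lower, and in tamoxifen 505 genes, 147 higher and 358 lower. CEACAM5 rose by 3.56 ± 0.17, TSPAN1 by 3.41 ± 0.19 and CEACAM6 by 2.90 ± 0.19 in E2. CENPT rose by at least 1.73, TSPAN1 by 3.11 ± 0.19 and CDSN by 2.71 ± 0.23 in tamoxifen. The metallothionein gene MT1G was lower by -1.54 ± 0.30 in E2, a call lost in 3 of the 6 fits that left out 1 array (adjusted p up to 0.0894, without E2 +Tet replicate 1), and members of this family have near-identical copies. In tamoxifen the histone gene H2BC14, also one of near-identical copies, changed by -2.04 ± 0.33, SNORA65 by -1.99 ± 0.36 and PGM5 by -1.82 ± 0.21. Mitosis and G2/M genes fell in both, 10 of 28 in E2 with a median of -0.517 (camera adjusted p = 0.00692 with an estimated correlation) and 27 of 28 in tamoxifen with a median of -1.058 (camera adjusted p = 5.4e-05 with an estimated correlation), and 22 and 28 were lower when adjusted over the list alone. Of 31 replication genes 2 were lower in E2, with a median of -0.35 (camera adjusted p = 1.44e-10, but adjusted p = 0.0787 with an estimated correlation), and 19 in tamoxifen, with a median of -0.747 (camera adjusted p = 0.00101 with an estimated correlation). Adjusted over the list alone, 11 and 27 were lower. Of the 26 AP-1 target genes 2 were higher in E2 (camera adjusted p = 0.00798, but adjusted p = 0.416 with an estimated correlation) and 4 in tamoxifen (camera adjusted p = 7.05e-05, but adjusted p = 0.0934 with an estimated correlation), and 4 and 4 were higher when adjusted over the list alone. Across the 3 treatments 64 genes were higher in -Tet in every one and 33 were lower, CENPT, TSPAN1, SNAI2, MMP13, IL6 and AGR2 among the former and CDC20, PLK1 and TFF3 among the latter. After quantile normalization the splits were 212 higher and 115 lower in E2, and 241 higher and 283 lower in tamoxifen. The E2 count was 163, 114 and 140 without E2 +Tet replicates 1, 2 and 3, and 110 and 131 without E2 -Tet replicates 1 and 3. The tamoxifen count was 330 without tamoxifen +Tet replicate 1 and 336 without tamoxifen -Tet replicate 3. With only the arrays compared in the fit the counts were 337 in vehicle, 277 in E2 and 197 in tamoxifen. Tamoxifen then gave the fewest genes of the 3 treatments instead of the most, so that their order depends on the fit.

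**Figure D2:**
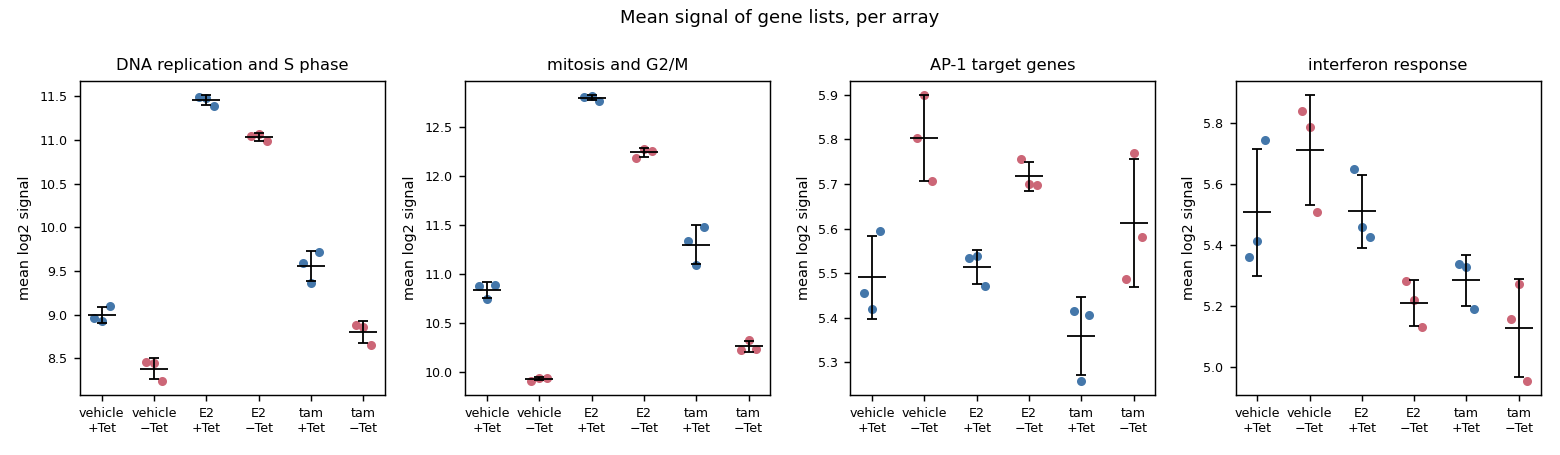
Mean log2 signal (y axis) of 4 gene lists on each array of the 6 groups (x axis), with points for single arrays, blue for +Tet and red for -Tet, and bars for the mean and SD of 3 arrays. The mitosis and G2/M list averages 10.83 in vehicle +Tet and 9.93 in vehicle -Tet, and 12.80 and 12.24 in E2.

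E2 raised classical estrogen receptor targets in both states. GREB1, a cofactor of the receptor, rose by 6.37 ± 0.20 in +Tet (adjusted p = 4.44e-17) and by 7.06 ± 0.20 in -Tet (adjusted p = 3.56e-18), from 11.26 ± 0.20 (SD, n = 3) to 17.63 ± 0.07 (SD, n = 3) in +Tet. PGR, the progesterone receptor gene, rose by at least 3.06 and 2.69, MYC by 3.23 ± 0.23 and 2.95 ± 0.23, TFF1 by 1.27 ± 0.12 and 1.45 ± 0.12, and CCND1, which encodes cyclin D1, by 0.56 ± 0.12 and 0.57 ± 0.12. TFF1 had reached 19.56 in E2 +Tet, where the highest value of the table was 19.93, so that its change can be understated. Of 34 estrogen-induced genes 32 rose in +Tet and 31 in -Tet, and none fell, with medians of 2.232 and 1.858 (camera adjusted p = 1.3e-05 and 6.28e-06 with an estimated correlation). Adjusted over the list alone, 32 and 33 rose. Of 11 estrogen-lowered genes 9 fell in +Tet and 7 in -Tet, among them EFNA1, at -2.67 ± 0.17 and -2.72 ± 0.17, and TP53INP1, at -2.67 ± 0.20 and -3.19 ± 0.20 (camera adjusted p = 0.000906 and 0.000875 with an estimated correlation), and 10 fell in each when adjusted over the list alone.

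**Figure D3:**
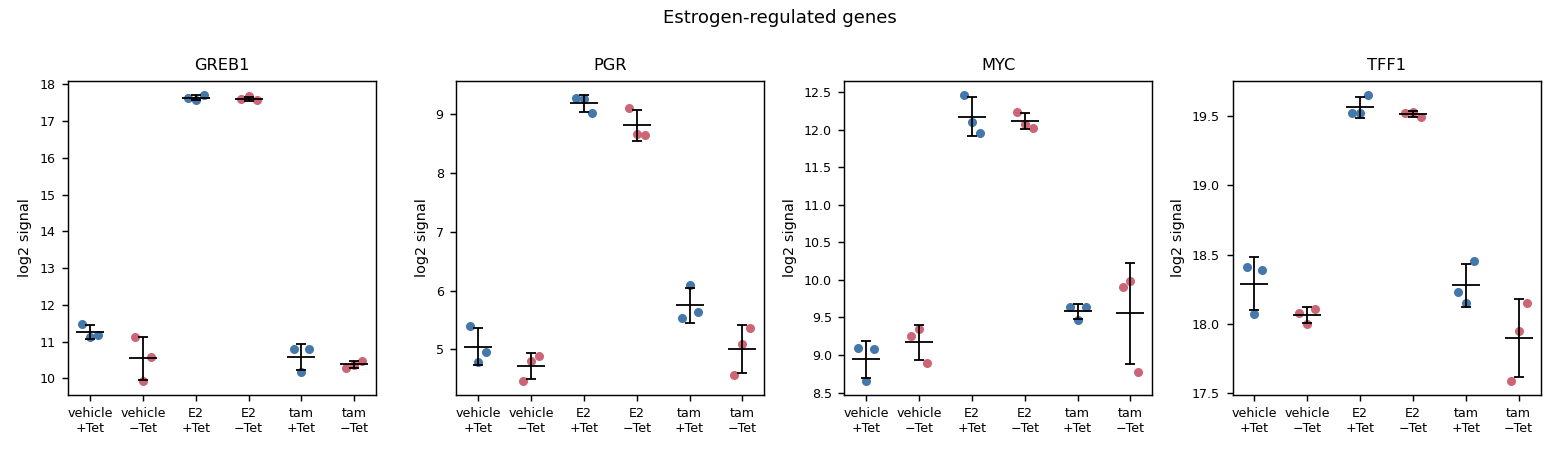
Log2 signal (y axis) of GREB1, PGR, MYC and TFF1 on each array of the 6 groups (x axis), with points for single arrays, blue for +Tet and red for -Tet, and bars for the mean and SD of 3 arrays. GREB1 averages 17.63 and 17.61 in the E2 groups and lies between 10.38 and 11.26 in the other groups.

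All 31 measured genes of DNA replication and S phase and all 28 of mitosis and G2/M rose with E2 in both states. Median changes were 2.427 in +Tet and 2.643 in -Tet for replication, and 1.887 and 2.292 for mitosis. CDC45, part of the replicative helicase, rose by at least 3.54 and 3.35, TK1 by 3.08 ± 0.17 and 3.59 ± 0.17, TOP2A by 2.33 ± 0.13 and 2.84 ± 0.13, and the kinesin KIF11 by 2.41 ± 0.16 and 2.78 ± 0.16. In the sterol and lipid synthesis list 12 of 26 members rose in +Tet and 13 in -Tet, and 1 fell in each, with ACAT2 up by 1.44 ± 0.16 and 1.59 ± 0.16 and EBP up by 1.12 ± 0.14 and 1.65 ± 0.14. That list passed with an estimated correlation in -Tet (adjusted p = 0.0147) but not in +Tet (adjusted p = 0.0883), and adjusted over the list alone 16 and 14 rose and 1 fell in each. Interferon response genes had a median of -0.077 in +Tet, where 2 of 29 rose and 1 fell (camera adjusted p = 0.832), and of -0.497 in -Tet, where 7 fell and none rose (camera adjusted p = 0.000642, but adjusted p = 0.188 with an estimated correlation). In -Tet 9 fell when adjusted over the list alone, and in +Tet 2 rose and 1 fell. Other genes with large rises were MYB, at 5.01 ± 0.21 and 4.85 ± 0.21, TMEM164, at 4.96 ± 0.23 and 4.99 ± 0.23, and SYTL5, at 4.64 ± 0.19 and 4.87 ± 0.19. Large falls were those of the GABA receptor gene GABBR2, at -4.91 ± 0.19 and -4.56 ± 0.19, the epidermal transcription factor gene GRHL3, at -4.19 ± 0.19 and -3.40 ± 0.19, and the interleukin receptor gene IL1R1, at -3.51 ± 0.29 in +Tet and with a fall of at least 3.07 in -Tet. UPK1A fell by at least 3.67 and 2.19, to a signal not above the negative controls. SNAI2 changed by -2.69 ± 0.23 and -4.04 ± 0.23.

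E2 changed 3521 genes in +Tet, 1755 higher and 1766 lower, and 3191 genes in -Tet, 1610 higher and 1581 lower. Both lists shared 1242 genes among those higher, where independent lists would share 84.1, and 1057 among those lower, where independent lists would share 83.1. No gene was called in opposite directions. Numbers for independent lists, here and below, are drawn over all 33616 genes, of which 10475 had a mean above the negative controls. If dim genes are called less often, these numbers are understated. Across genes, which are not independent replicates, the changes in the 2 states correlated at r = 0.781, and no array was shared between them.

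**Figure D4:**
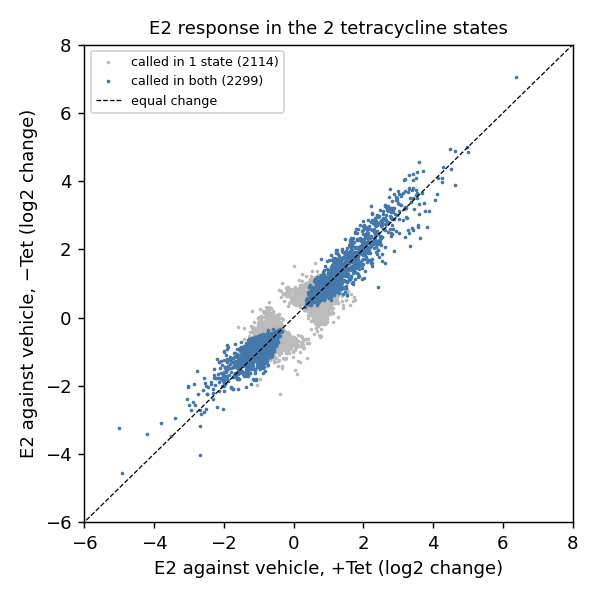
Log2 change with E2 in +Tet (x axis) against that in -Tet (y axis), for genes called in both states (blue, 2299 genes) or in 1 state (grey, 2114 genes), with the dashed line of equal change. Genes called in both lie along the line, with GREB1 farthest out at 6.37 and 7.06.

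Tamoxifen changed fewer genes than E2 did, 163 in +Tet (100 higher, 63 lower) and 282 in -Tet (97 higher, 185 lower). STC1, which encodes the hormone stanniocalcin, rose by 2.44 ± 0.23 in +Tet (adjusted p = 7.69e-07) and 2.09 ± 0.23 in -Tet (adjusted p = 8.66e-06), and SYTL5 rose by 2.43 ± 0.19 and 2.42 ± 0.19. AGR2, a protein disulfide isomerase of secretory cells, rose by 2.29 ± 0.17 in +Tet (adjusted p = 1.01e-08) and 1.15 ± 0.17 in -Tet (adjusted p = 0.000338). The calcitonin receptor gene CALCR rose by 1.35 ± 0.21 in +Tet and 1.99 ± 0.21 in -Tet and RASGRP1 by 1.32 ± 0.18 and 1.67 ± 0.18. RLN2, which encodes relaxin, rose by 1.89 ± 0.24 in +Tet and by at least 1.14 in -Tet. The non-coding LINC01291 rose by 2.04 ± 0.25 and 1.98 ± 0.25. In +Tet and -Tet UPK1A changed by -2.04 ± 0.24 and -1.77 ± 0.24, the carnitine transporter gene SLC22A5 by -1.88 ± 0.21 and -1.65 ± 0.21, RCAN1 by -1.79 ± 0.20 and -1.53 ± 0.20, and the sterol transporter gene ABCG1 by -1.63 ± 0.18 and -1.41 ± 0.18. MIR4521 changed by -2.07 ± 0.26 in +Tet and -2.59 ± 0.26 in -Tet, and the small nucleolar RNAs SNORA65 by -2.97 ± 0.36 and SNORD24 by -1.83 ± 0.25 in -Tet. In +Tet these RNAs stood at -0.70 ± 0.36 (adjusted p = 0.656) and -0.88 ± 0.25 (adjusted p = 0.157). The SNORA65 difference between the states in tamoxifen was not called without both arrays of lowest weight. The classical targets did not pass the test with tamoxifen in either state: GREB1 stood at -0.67 ± 0.20 and -0.17 ± 0.20, MYC at 0.64 ± 0.23 and 0.39 ± 0.23, TFF1 at -0.01 ± 0.12 and -0.17 ± 0.12, and CCND1 at -0.26 ± 0.12 and -0.15 ± 0.12. PGR was not above the negative controls in vehicle or tamoxifen. ESR1 stood at -0.71 ± 0.33 and -0.60 ± 0.33.

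Replication and mitosis lists also rose with tamoxifen in both states, the estrogen-induced list rose in +Tet, and the estrogen-lowered list fell in -Tet. DNA replication genes had medians of 0.607 in +Tet, where 8 of 31 rose, and 0.41 in -Tet, where 7 rose (camera adjusted p = 0.00151 and 0.00656 with an estimated correlation), and 19 and 16 rose when adjusted over the list alone. Mitosis and G2/M genes had medians of 0.447 and 0.307 with 2 of 28 called in each (camera adjusted p = 0.00151 and 0.011 with an estimated correlation), and 19 and 11 rose when adjusted over the list alone, MKI67 standing at 0.97 ± 0.16 and 0.85 ± 0.16. The MKI67 call in -Tet was lost without vehicle -Tet replicate 2 (adjusted p = 0.109) and without tamoxifen -Tet replicate 3 (adjusted p = 0.0663). The other called member, CCNB2 in +Tet and TOP2A in -Tet, lost its call in 6 of the 6 fits that left out 1 array, with adjusted p values of up to 0.215 without vehicle +Tet replicate 3 and 0.135 without vehicle -Tet replicate 3. Of 34 estrogen-induced genes 7 rose in +Tet, with a median of 0.307 (camera adjusted p = 0.0119 with an estimated correlation). In -Tet 8 rose, but the median was 0.027 with 17 of 34 above 0 (camera adjusted p = 2.01e-07, but adjusted p = 0.0503 with an estimated correlation). Adjusted over the list alone, 12 and 8 rose and 1 fell in each. The amino acid transporter gene SLC7A5 rose by 1.52 ± 0.13 in +Tet and 1.17 ± 0.13 in -Tet, TPD52L1 by 1.43 ± 0.14 and 1.34 ± 0.14 and the chaperone gene HSPB8 by 1.76 ± 0.19 and 1.41 ± 0.19. Of 11 estrogen-lowered genes 2 fell in -Tet, with a median of -0.42 (camera adjusted p = 0.0457 with an estimated correlation), and 0 in +Tet, with a median of -0.297 (camera adjusted p = 0.00495, but adjusted p = 0.181 with an estimated correlation). Adjusted over the list alone, 6 and 3 were lower. In the sterol and lipid synthesis list 1 of 26 members rose in +Tet and 7 in -Tet, MSMO1 by 0.60 ± 0.12 and 0.81 ± 0.12, and EBP by 0.80 ± 0.14 in -Tet (camera adjusted p = 0.0374 and 0.00656 with an estimated correlation), and 5 and 13 rose when adjusted over the list alone. EBP had an adjusted p of 0.0522 without vehicle -Tet replicate 2. In -Tet 5 of 29 interferon response genes fell and none rose, with a median of -0.503 (camera adjusted p = 0.0338 with an estimated correlation), IFIT1 by at least 0.37 and SAMD9 by at least 0.80. In +Tet 0 of 29 were called, with a median of -0.2 (camera adjusted p = 0.0413, but adjusted p = 0.461 with an estimated correlation). In -Tet 11 fell when adjusted over the list alone, and 0 did in +Tet. The E2 and tamoxifen values in -Tet rest on the same vehicle -Tet arrays. The mean level of 9 of the 29 members lay above the negative controls.

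The tamoxifen counts moved when 1 array was left out. In -Tet they moved in both directions, while in +Tet each array left out lowered the count, to between 100 and 133. In -Tet the count was 91 without vehicle -Tet replicate 2, 145 without vehicle -Tet replicate 1, 149 and 160 without tamoxifen -Tet replicates 1 and 3, and 363 without tamoxifen -Tet replicate 2. In +Tet it was 106, 104 and 105 without vehicle +Tet replicates 1, 2 and 3, and 100 without tamoxifen +Tet replicate 3. After quantile normalization the splits were 158 higher and 59 lower in +Tet, and 172 higher and 132 lower in -Tet, and centring of each array on its median gave 119 higher and 130 lower in -Tet. Tamoxifen -Tet replicate 1 and tamoxifen +Tet replicate 2 had the lowest array weights, 0.54 and 0.73. Without both of them, a choice made after seeing the data, the counts were 152 in +Tet and 161 in -Tet. With only the arrays compared in the fit they were 142 in +Tet and 92 in -Tet, and with array weights 230 and 200. Which state gave more genes with tamoxifen thus depends on the fit. Across genes, the changes in the 2 states correlated at r = 0.381, with 61 genes higher in both, where independent lists would share 0.289, and 38 lower in both, where they would share 0.347.

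Within a state, the E2 and tamoxifen changes rest on the same vehicle arrays. Their correlation across genes was r = 0.502 in +Tet and 0.468 in -Tet, and unchanged groups simulated against shared controls gave 0.501. The covariance was 0.0627 in +Tet and 0.0619 in -Tet against 0.0243 in the simulation, which leaves differences of 0.0384 and 0.0375. With 3 vehicle arrays per state the controls were not split, so that part of any excess in the shared calls may come from them. In +Tet 87 genes were higher with both ligands (5.22 for independent lists) and 49 lower with both (3.31 for independent lists), and in -Tet 84 were higher (4.65) and 124 lower (8.7). In opposite directions 5 genes were called in +Tet and 15 in -Tet. In simulated unchanged groups 0 genes were called with both. Without changed genes hardly any call is made with either ligand, so this count could not show how many shared calls come from the shared arrays.

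Set directly against E2, tamoxifen gave lower signals of proliferation and estrogen-induced genes. All 31 replication genes and all 28 mitosis genes were lower with tamoxifen in both states, with medians of -1.837 and -2.163 for replication and -1.393 and -1.998 for mitosis. Of 34 estrogen-induced genes 27 were lower and 1 was higher in +Tet, with a median of -1.63, and 32 were lower and none higher in -Tet, with a median of -1.688 (camera adjusted p = 2.23e-05 and 9.66e-06 with an estimated correlation). In each state 32 were lower when adjusted over the list alone. GREB1 was lower by -7.04 ± 0.20 in +Tet and -7.23 ± 0.20 in -Tet. The cytokine gene IL20 was lower by at least 2.92 in +Tet and 1.96 in -Tet and the early growth response gene EGR3 by at least 3.28 and 2.92, both to signals not above the negative controls with tamoxifen. GABBR2 was higher with tamoxifen by 3.98 ± 0.19 and 3.67 ± 0.19, GRHL3 by 3.48 ± 0.19 and 2.51 ± 0.19, and SNAI2 by 1.94 ± 0.23 and 2.97 ± 0.23. In +Tet 2573 genes differed, 905 higher and 1668 lower with tamoxifen, and in -Tet 2474, 717 higher and 1757 lower. After quantile normalization the splits were 1379 higher and 1504 lower, and 1332 higher and 1445 lower.

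Whether the ligand responses themselves differed between the states was tested as an interaction. No gene passed limma's test in the E2 interaction, where 1662 genes had an unadjusted p under 0.05 and 1681 would by chance, and none passed in the tamoxifen interaction, where 1131 did. The smallest adjusted p values were 0.4262, for TGFBI with E2, and 0.7114, for AGR2 with tamoxifen. GREB1 differed by 0.69 ± 0.29 between the E2 responses (adjusted p = 0.994) and MYC by -0.28 ± 0.33. In simulated data, interactions of 1 on the log2 scale were recovered in 20% of changed genes for E2 and 28% for tamoxifen, and interactions of 2 in 90% and 84%. Differences of about 1 were thus mostly beyond detection with 3 arrays per group. These simulations called 106 and 109 genes, against 0 in the data, and the adjusted threshold tightens when fewer genes pass. The shares can therefore be overstated if few genes differ.

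Some lists shifted in the interactions only with camera's preset correlation. Mitosis and G2/M genes had a median E2 interaction of 0.357, a larger rise in -Tet (camera adjusted p = 7.24e-10, but adjusted p = 0.103 with an estimated correlation), TTK standing at 0.85 ± 0.24. Interferon response genes had a median of -0.377 with E2 (adjusted p = 0.103 with an estimated correlation), and of -0.237 with tamoxifen (adjusted p = 0.679 with an estimated correlation). Of these, IFIT1 and SAMD9 lay above the negative controls in vehicle -Tet only. No member of these lists passed the test over all genes.

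The fibroblast, immune and endothelial markers had median levels of 3.52, 3.92 and 3.44, near the negative controls. Over all 11 comparisons, the fibroblast list had a lowest camera adjusted p of 0.163 and the immune list one of 0.248. The fibroblast list member LUM was among the 64 genes higher in -Tet in all 3 treatments, and no member of that list was called lower in any comparison. Endothelial markers had a median of -0.22 in -Tet against +Tet in vehicle (camera adjusted p = 0.0457, but adjusted p = 0.24 with an estimated correlation), a call lost in 4 of the 6 fits that left out 1 array (adjusted p up to 0.276, without vehicle +Tet replicate 1). Ribosomal protein genes and mitochondrially encoded genes, which watch array and RNA quality, had lowest camera adjusted p values of 0.0855 and 0.25. These tests compare groups and do not show single poor arrays. The mean ribosomal signal was 15.55 on tamoxifen -Tet replicate 1 and 15.67 on tamoxifen +Tet replicate 2, the arrays of lowest weight. It was 15.59 on E2 -Tet replicate 1, whose weight was 1.01, and between 15.75 and 16.03 on the other arrays. Basal epithelium and growth factor receptor lists passed in no comparison, with lowest camera adjusted p values of 0.148 and 0.343. Luminal epithelium, mesenchymal and EMT, AP-1 subunit, unfolded protein, NF-kappaB, hypoxia and BCL2 family lists passed in 4, 3, 3, 3, 4, 1 and 3 of the comparisons with the preset correlation and in 0 with an estimated one, where their lowest adjusted p values were 0.494, 0.131, 0.317, 0.353, 0.188, 0.461 and 0.257.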

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

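The tests of the JUN, CENPT and interferon patterns and the splits of the interactions were chosen after their results had been seen. List shifts that differed between the tetracycline states were picked out where camera with a preset correlation gave an adjusted p under 0.05 for an interaction. With E2 these were mitosis and G2/M, at a median of 0.357, DNA replication, at 0.24, sterol and lipid synthesis, at 0.183, and the interferon response, at -0.377. With tamoxifen they were sterol and lipid synthesis, at 0.167, and the interferon response, at -0.237. None passed with an estimated correlation, where adjusted p values ran from 0.103 to 0.679.

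For the interferon response with E2, a single vehicle array as the cause is argued against, since the median stayed at or below -0.315 without each of them. Rows near background are argued against only in part. The 9 of 29 members whose mean over all arrays lay above the negative controls had a median of -0.507. That median was not tested, and a single group of such a member can lie lower, as OAS1 did in E2 -Tet at 5.66. Background is thus not excluded. A higher level in vehicle -Tet alone stays open. In vehicle, -Tet against +Tet gave a median of 0.16 with 2 of 29 members higher (camera adjusted p = 0.00179, but adjusted p = 0.24 with an estimated correlation), and in tamoxifen one of -0.173 (adjusted p = 0.964 with an estimated correlation). The same contrast within E2 gave a median of -0.273, but that shift did not pass with an estimated correlation (adjusted p = 0.416), and without E2 +Tet replicate 1 the preset test gave an adjusted p of 0.0861. A biological difference between the states is among the open explanations and was not tested apart from the presence of tetracycline.

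JUN was not higher on arrays labelled -Tet, at -0.36 in vehicle. An exchange of the labels of both states is argued against by the AP-1 target list, of which 9 called values over the 3 treatments were higher in -Tet and none was lower. These came from 4 genes, MMP13 and IL6 in all 3 treatments, ITGA2 in vehicle and tamoxifen and PLAU in tamoxifen, and the list as a whole passed with an estimated correlation in vehicle (adjusted p = 0.0337) but not in E2 (0.416) or tamoxifen (0.0934). This rests on the premise that c-Jun raises these genes. The AP-1 subunit list, which holds JUN itself, leaned the other way. Its mean level was 6.81 in +Tet and 6.72 in -Tet in vehicle, 6.59 and 6.27 in E2, and 6.61 and 6.36 in tamoxifen. In E2 its median change was -0.263 (camera adjusted p = 0.0106 with the preset correlation), a call lost in 2 of the 6 fits that left out 1 array. With an estimated correlation it passed in no comparison (lowest adjusted p = 0.317). A wrong tetracycline label on a single array is argued against as well: 0 of 18 arrays lay nearer to the other state of their treatment, over 200 genes chosen without that array. Whether the JUN row reads the vector's transcript cannot be told apart from a lack of induction in the RNA, because the parts of the transcript it reads are not given in the sources used here.

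CENPT rose in -Tet in vehicle from 3.68, not above the negative controls, to 7.71, at least 1.59 above their 95th percentile, while THAP11, which overlaps it, was called lower at -1.22 (adjusted p = 0.0177) between groups that were both below that percentile, at 4.48 in -Tet and 5.70 in +Tet. A rise of the whole neighbourhood is argued against, since 21 other protein-coding genes within 200 kb had a median change of -0.17, between -0.56 and 0.46, and 0 of them were called. Noise near background is argued against by the mean of 7.33 over -Tet arrays, above the 95th percentile of the negative controls at 6.12. That mean includes the vehicle arrays whose difference singled the gene out. The tamoxifen -Tet arrays, not part of that difference, stood at 7.85 ± 0.08 (SD, n = 3). The signal was nearest to that percentile in E2 -Tet, at 6.42 ± 0.54 (SD, n = 3), where replicate 3 lay below it at 5.81 and the rise was at least 0.30. Signal shared with THAP11 stays open, because differences between groups at that level are not read as changes. An effect of the vector on this gene, or of c-Jun, may also underlie it and was not tested.

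Other splits of the arrays were counted for each comparison, with only the arrays compared in the fit. A comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05, and in each of the 9 such comparisons 1 split, the real one, gave as many genes. The real and the highest other counts were 337 and 1 for -Tet against +Tet in vehicle, 277 and 1 in E2, and 197 and 0 in tamoxifen. They were 3865 and 0 for E2 in +Tet, 3241 and 0 for E2 in -Tet, 142 and 0 for tamoxifen in +Tet and 92 and 0 in -Tet, and 2380 and 1 for tamoxifen against E2 in +Tet and 1804 and 0 in -Tet. Every other split mixes arrays of both real groups, so that a real difference widens the spread within its groups and lowers its count. The low other counts are therefore not those of unchanged arrays. For the interactions the real count was 0, which each of the 100 splits drawn must reach, so that their number decides nothing. The highest other count with E2 was 84, in a split that kept the E2 label on 3 of 3 E2 arrays in +Tet and on 1 of 3 in -Tet and so holds part of the E2 response itself. The highest other count for tamoxifen was 2.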

How the results depend on the processing

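Of 145 calls of named genes, 0 changed sign and 18 were lost under at least 1 alternative other than the block, among those run for single genes. These were quantile normalization, centring, the mean of all rows, genes above the median gene, the block, and fits without single arrays or the 2 of lowest weight. The prior without trend, array weights, the fold minimum, only the arrays compared and genes above the negative controls were run for counts alone. Counts that moved by over 1.5 times were those of -Tet against +Tet in E2 (266; 171 without a trend, 417 among genes above the negative controls), in tamoxifen (505; 766 above the negative controls, 197 with only the arrays compared), of tamoxifen in +Tet (163; 254 above the negative controls) and of tamoxifen in -Tet (282; 149 without a trend, 509 above the negative controls, 92 with only the arrays compared, 161 without the 2 arrays of lowest weight). Fewer genes tested lowers the burden of adjustment above the negative controls; the cause was not tested for the others. That filter and the arrays of lowest weight were chosen after seeing the data. Leaving out 1 array gave 190 to 224 genes for -Tet against +Tet in vehicle, 110 to 208 in E2 and 330 to 537 in tamoxifen, 100 to 133 for tamoxifen in +Tet and 91 to 363 in -Tet, and 0 to 1 for the tamoxifen interaction. The correlation of the E2 changes between the states was 0.875 among genes with a mean above the median gene, and that of the tamoxifen changes 0.537, against 0.781 and 0.381 over all genes. Leaving out 1 array gave 0.744 to 0.776 for E2.

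The replicate numbers do not pair the arrays: of 45 pairs with the same number 3 had deviations correlated above 0.1, and 7 of 18 arrays correlated best with their own number. With the replicate number as a block the counts were 295, 229 and 467 for -Tet against +Tet in vehicle, E2 and tamoxifen, 3450 and 3094 for E2, 142 and 257 for tamoxifen, 0 for both interactions, and 2524 and 2389 for tamoxifen against E2. The calls of TM7SF2 in vehicle (adjusted p = 0.0565), CCNB2 with tamoxifen in +Tet (0.0547), endothelial markers in vehicle (0.0501) and the BCL2 family with E2 in -Tet (0.0521) were lost, and CDK1 with tamoxifen in -Tet was gained (0.0482); no other call of a named gene or list changed. The signal over background limits the rest: 10475 of 33616 genes lay above the 95th percentile of the negative controls.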

Other observations

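Both hypotheses here were written down before the genes that test them were looked at, though each came from genes already seen. Metallothionein genes, which encode metal-binding proteins, were among the largest E2 changes: MT1G rose by 3.82 ± 0.30, MT1X by 3.20 ± 0.31 and MT2A by 2.94 ± 0.18 in +Tet. Of 6 other family members 4 rose with E2 in +Tet, MT1M by 2.52 ± 0.26, MT1F by 2.15 ± 0.23, MT1H by at least 1.37 and MT1E between groups not above the negative controls, and kept their direction under quantile normalization and centring. MT3 and MT4 did not pass, but their mean levels of 4.31 and 4.59 were not above the negative controls, so that the test rests on MT1M, MT1F and MT1H. The hypothesis that much of the family may rise together with E2 is consistent with this count, but near-identical copies can share probes, so the members are not independent.

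CYP1A1, a target of the aryl hydrocarbon receptor, was higher on vehicle arrays labelled -Tet by 2.37 ± 0.21 and CYP1B1 by 0.64 ± 0.12. In E2 and tamoxifen CYP1A1 was also called, at 1.70 ± 0.21 and 1.53 ± 0.21. CYP1B1 was not, at 0.31 ± 0.12 (adjusted p = 0.321) and 0.41 ± 0.12 (adjusted p = 0.118). A rise of such targets as a group could have been the reason, but 0 of 3 other listed targets above the negative controls were called: TIPARP stood at 0.20 ± 0.16, NQO1 at 0.12 ± 0.11 and NFE2L2 at 0.08 ± 0.16. With 3 genes the test is weak, and NFE2L2 is less established as a target than the others. The receptor's own gene, AHR, changed in the same direction as CYP1A1. It was among the 64 genes higher in -Tet in all 3 treatments, by 0.85 ± 0.13 in vehicle. It is not one of the listed targets and so does not test whether they rise as a group.

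Of the 1119 rows with several gene symbols, which no comparison used, 31 were called between the states in vehicle, 177 with E2 in +Tet and 171 in -Tet, 12 with tamoxifen in +Tet and 16 in -Tet. In the E2 interaction 1 such row was called, adjusted over those rows alone.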
